A study of Drosophila melanogaster with 4 samples.

How the data were processed

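RNA from whole Drosophila melanogaster larvae of the third instar was sequenced in 4 libraries, 2 from control larvae and 2 from larvae homozygous for an insertion allele of ski3. The titles of the samples gave the groups and the replicate numbers. The strain field of the labels names CantonS and the sample descriptions name w1118, so the background of the controls is not settled here. Any difference in background between the groups could not be told apart from an effect of the mutation. The labels do not say whether replicates came from separate collections of larvae, so p-values of single genes measure only the spread between these samples.

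The deposited files are transcript assemblies in the format of Cufflinks, with 1 FPKM value (fragments per kilobase of transcript, scaled to the fragments mapped) per transcript, per the file headers and attribute fields. The submitters' processing notes name Bowtie2 2.3.4.1, TopHat2 with the same version number, and the genome build BDGP6. The version of Cufflinks is not given in the sources used here. The files hold no read counts, so the depth of each library is unknown and no counting interval was computed.

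Each file lists a reference annotation of up to 28704 transcripts and between 9361 and 9766 newly assembled ones. The reference transcripts and the assembled ones were found to lie on different coordinates. Of the introns of assembled transcripts, between 82.9% and 84.2% were introns of the Ensembl 115 annotation of BDGP6.54, against 22.7% of those of the reference transcripts, and 13.9% to 14.0% of the reference transcripts had the place and exons that BDGP6.54 gives them. Gene values summed by the deposited transcript names therefore do not measure the named genes on most chromosome arms. Across 10124 genes in control 1, they correlated with values by position at r = 0.25 on the log2 scale, with r = 0.93 on arm 2L and r = -0.04 on arm 2R. These correlations are across genes, which are not independent replicates.

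The gene value fixed before the data were examined, the sum of FPKM over transcripts by name, was for this reason replaced. Each gene's value was the sum over transcripts of FPKM times the share of the gene's own exon bases that the transcript covered. Own bases are those in exons of only 1 gene. A gene needed at least 100 own bases that made up at least 20% of its exon bases, which 16297 of 17873 genes had. Strand was ignored, so overlapping and antisense genes are separated only through their own bases, and near-identical copies can share reads.

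Many genes that every cell uses are listed at 0 in 1 library and at high values in the others, so a 0 can be a failed assembly. Among genes measured at 10 FPKM or more in the other 3 libraries, 0.861% to 1.88% were listed at 0 in the remaining library. In mutant 2, 36 mitochondrial reference transcripts present in the other files are missing, and no mitochondrially encoded gene was tested. A gene was therefore called measured in a library where transcripts above 0 covered at least 50% of its own bases and at least 50% of its value came from transcripts lying by at least 50% of their length within it. Genes measured in all 4 libraries with a mean of at least 1 FPKM were tested, 5239 in number, of which 5179 code for protein. They are weighted towards arm 2L, with 1700 there, 906 on 2R, 912 on 3L, 1039 on 3R and 654 on X. By contrast, 2L held 1950 and 2R 2094 of the genes with a mean of at least 1 FPKM by position or by name. The filter removes genes that were truly silent in 1 group.

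The gene value and the criteria for a measured gene were chosen after the data were seen. Calls had been counted for 8 other combinations of gene value and treatment of 0 before, and these gave between 1 and 115 genes higher and between 0 and 145 lower. The criterion on transcripts within the gene was added because merged transcripts spread over neighbouring genes, and its own calls had not been seen then. With it, the correlation of the log2 values between the 2 controls went from r = 0.96 over 6785 genes to r = 0.97 over 5239, and between the 2 mutants from r = 0.96 to r = 0.98.

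Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1). Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Gene lists written before the data were examined, 32 in number, were tested with limma's camera with a preset inter-gene correlation of 0.01 where at least 4 members were tested. At a preset correlation, camera takes its degrees of freedom from the number of genes and not of libraries. Genes within 2 Mb of Ski3 were compared with all others by Fisher's exact test. The genes named were fixed by rule before the data were examined. They are the Ski complex genes Ski3, tst and Ski8 and the white gene whatever their result, the 12 largest rises and 12 largest falls among genes that passed, with a mean of at least 5 FPKM and both mutant values outside the control range, and up to 4 members of each list that passed or had at least 3 members that passed. Other named genes are said to have been chosen after their values were seen.

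The gene test was tested on data simulated from limma's own variance model for 5239 genes. It recovered 30.4% of changes of 1 on the log2 scale, 84.0% of changes of 2 and 92.0% of changes of 3, and 3.44% of all calls were false. The list test recovered 50 of 50 lists shifted by 0.5 and called 0 of 240 unshifted ones, in simulations without correlation between genes. Smaller shifts, such as the medians of the ribosomal protein (0.28), lipid (0.22) and insulin (0.15) lists, were not simulated. Neither simulation includes failed assemblies. In all, 23 alternatives planned before the data were examined and 7 added afterwards were run. The pseudocount, filter, scaling, variance model, replicate block, libraries, gene value, threshold, list test and window were varied. Those fixed before were run on the replaced gene values, and the alternative without a filter kept the criteria for a measured gene.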

Results

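Gene expression in whole larvae of the third instar was compared between 2 control libraries and 2 libraries from ski3 homozygous mutants. Ski3 is a subunit of the Ski complex, which feeds RNA to the cytoplasmic exosome for decay from the 3' end. FPKM values were assigned to genes by position on BDGP6.54, and 5239 genes were measured in all 4 libraries. Values are means ± SD in FPKM with n = 2 libraries per group, and changes are log2 differences of FPKM + 1, mutant minus control. The depth of the libraries is unknown. Log2 values correlated across genes at r = 0.97 between the controls, at r = 0.98 between the mutants and at r = 0.93 to 0.96 between groups.

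The targeted gene could not be read. Ski3 (CG8777, FBgn0033376, arm 2R, 9098539 to 9103153) was listed at 0 in both controls, at 1.06 in mutant 1 and at 0.642 in mutant 2. The transcripts above 0 covered 36.4% and 20.2% of its own exon bases in the mutants and did not lie mainly within it, so it counted as measured in no library and the labels were not checked by it. The Ski complex helicase gene tst (FBgn0039117) was listed at 0, 0.21, 0 and 0 in controls 1 and 2 and mutants 1 and 2. The gene taken as Ski8 (CG3909, FBgn0027524) had values of 0, 7.48, 20.3 and 5.87 in the same order and was measured in mutant 1 only. The white gene w (FBgn0003996), used as a marker in many fly insertions, had 1.48 and 2.47 in the controls, 0.766 in mutant 1 and 0 in mutant 2, and was measured in the controls only. None of these 4 genes was tested. If the controls were w1118 and the insertion carried white, w would be higher in the mutants, and its low values went the other way. These values do not settle the background of either group. Of the fixed list of Ski complex and RNA exosome genes, 7 were tested and 0 passed (limma, adjusted p), with a median change of -0.19.

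The comparison asked which genes differ between mutant and control larvae, and 50 genes were higher and 76 lower in the mutants with limma, over genes that met criteria chosen after the data were seen. The largest rise was in LysX, a lysozyme gene (FBgn0004431, 3L, 1194739 to 1195302), with 8.70 ± 2.01 in controls and 177 ± 6.87 in mutants, a change of 4.21 ± 0.18 (SE; adjusted p = 0.011). CG12780 (FBgn0033301, 2R, 8551859 to 8552290) rose from 5.52 ± 0.84 to 96.3 ± 9.24, a change of 3.90 (adjusted p = 0.011). The cytochrome P450 gene Cyp4e3 (FBgn0015035, 2L, 9747839 to 9750071) rose from 0.564 ± 0.12 to 12.6 ± 1.50. Gycalpha99B, which encodes a subunit of soluble guanylyl cyclase, rose from 3.36 ± 0.81 to 28.5 ± 2.35, and the odorant receptor gene Or30a from 1.15 ± 0.45 to 13.5 ± 0.37. The remaining 7 of the 12 largest rises were CG13063, CG45061, CG33459, CG15236, CG7191, CG14022 and CG8665, with changes from 2.62 in CG13063 to 1.75 in CG8665 (adjusted p between 0.022 and 0.045).

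The largest fall was in ebony (e, FBgn0000527, 3R, 21229839 to 21237177), whose enzyme joins beta-alanine to dopamine in cuticle tanning, from 262 ± 183 to 1.53 ± 1.12, a change of -6.58 ± 0.61 (SE; adjusted p = 0.026). Its controls had 392 and 132 and its mutants 0.731 and 2.32. The tyrosine hydroxylase gene ple (FBgn0005626, 3L, 6713356 to 6719525) fell from 121 ± 68.9 to 8.30 ± 3.15, a change of -3.63 (adjusted p = 0.048), with changes from -4.24 to -3.01 over 23 other settings, and passed in 6 of the 18 of these in which any gene passed. The ecdysone-inducible gene ImpE2 (FBgn0001254, 3L, 3510974 to 3512681) fell from 94.3 ± 2.04 to 12.6 ± 3.06. The cuticle protein gene Cpr65Av fell from 55.7 ± 0.013 to 5.36 ± 2.52, and BckdhB, a subunit of the branched-chain ketoacid dehydrogenase, from 60.5 ± 15.0 to 6.19 ± 0.46. On arm 2R, CG13560 (23747560 to 23748477) fell from 392 ± 37.6 to 27.1 ± 1.83 and CG11300 (23751915 to 23752495) from 765 ± 45.7 to 52.0 ± 17.0. The other 5 of the 12 were CG7906, CG14292, Had2, the cytochrome P450 gene Cyp4d8 and CG5171, with changes from -5.65 in CG7906 to -2.79 in CG5171. CG7906 had changes from -6.64 to -4.39 over 24 other settings and passed in 7 of the 19 in which any gene passed. LysX, with changes from 3.74 to 4.43, passed in all 19.

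**Figure D1:**
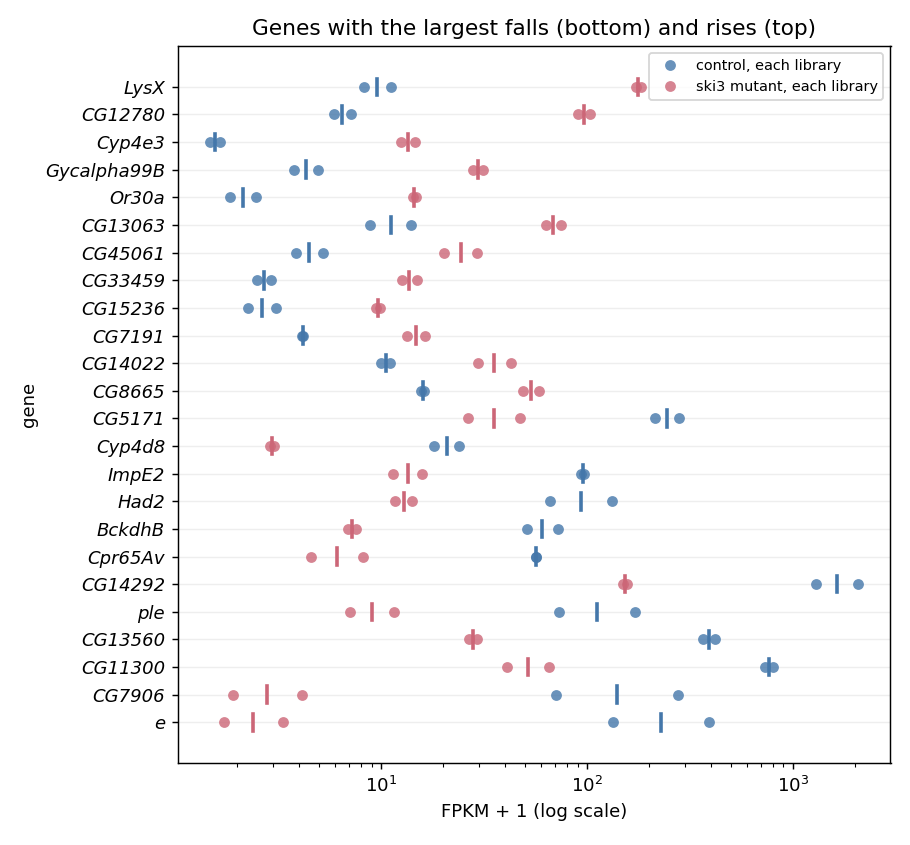
FPKM + 1 on a log axis for the 12 genes with the largest falls (bottom rows) and the 12 with the largest rises (top rows), with 1 point per library, controls in blue and mutants in red, and a short vertical line at the mean of the log2 values of each group. In each row both mutant points lie on the same side of both control points, and ebony (e) has the widest gap, from 132 and 392 in controls to 0.731 and 2.32 in mutants.

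The count of genes, and which genes it held, depended on the gene value, the treatment of 0 and the scaling. It was 5 higher and 4 lower with the coverage criterion alone, of which 3 and 2 were among the 50 and 76, 11 and 11 with a value above 0 in all 4 libraries (3 and 2 shared), 52 and 70 with every 0 kept as a value (5 and 7 shared), 29 and 37 with transcript names as deposited, which do not measure the named genes on most arms (5 and 11 shared), 8 and 19 with the most abundant transcript (6 and 15 shared) and 15 and 29 with the sum of assigned transcripts (11 and 21 shared). It was 22 and 46 without the variance trend, 58 and 56 after median-ratio scaling and 107 and 87 after quantile normalization, and 0 and 0 at a threshold of 0.01 with limma. With any 1 of the 4 libraries left out, 0 genes passed with limma, and between 655 and 1414 had an unadjusted p under 0.05, against 1334 with all 4. In these fits 1 group held 1 library that was assumed to vary like the other group. The changes of all 126 genes kept their sign in them, and the median size was 1.38 to 1.48 against 1.41 with all libraries, over genes chosen on the same libraries.

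The lists of carbohydrate and of lipid metabolism were higher in the mutants with camera at a preset correlation and not with an estimated one, and few of their genes passed singly. Of 17 tested genes of glycolysis, gluconeogenesis and trehalose, 15 had changes above 0, with a median of 0.70, 2 rose over all genes tested and 14 rose adjusted over the list alone. The list was higher than other genes with camera (adjusted p = 1.9e-09; adjusted p = 0.57 with an estimated correlation of -0.053). Gpo1, a glycerol-3-phosphate oxidase gene, rose from 28.1 ± 3.37 to 79.1 ± 1.67, and the glycogen phosphorylase gene Glyp from 649 ± 21.9 to 1213 ± 18.1. Of the 18 other settings in which any gene passed, Gpo1 passed in 14 and Glyp in 9. The pyruvate kinase gene PyK had 497 ± 103 and 1113 ± 34.5 (adjusted p = 0.056), and the trehalose synthesis gene Tps1 56.4 ± 3.01 and 98.2 ± 0.21 (adjusted p = 0.051). Of 21 genes of lipid storage and metabolism, 17 had changes above 0, with a median of 0.22, 1 rose over all genes and 7 rose adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.74 with an estimated correlation of 0.012). The gene that rose was Lsd-1, a lipid droplet coat protein gene, from 162 ± 7.41 to 294 ± 2.04, and it passed in 10 of the 19 other settings in which any gene passed. The fatty acid synthase gene FASN1 had 80.2 ± 13.1 and 183 ± 40.7, SREBP 63.8 ± 0.63 and 131 ± 26.1, and the carnitine palmitoyltransferase gene whd 55.4 ± 2.87 and 103 ± 12.1, and these 3 did not pass.

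Cytoplasmic ribosomal protein genes were higher as a list, with changes above 0 in 53 of 57 and a median of 0.28 (camera adjusted p = 7.4e-09; adjusted p = 0.83 with an estimated correlation), and 0 passed singly, over all genes or adjusted over the list alone. RpL11 had 889 ± 50.8 in controls and 1711 ± 560 in mutants and RpL14 2559 ± 829 and 4570 ± 748, while 2 members with other changes were RpL10Aa, at 9.03 ± 3.06 and 3.44 ± 0.40, and RpL22-like, at 22.1 ± 0.55 and 13.5 ± 13.9. The muscle list was higher with a median of 0.46 over 10 genes, of which 7 had changes above 0, 0 passed over all genes and 5 rose adjusted over the list alone (camera adjusted p = 0.0064; adjusted p = 0.95 with an estimated correlation). Its members Mhc, at 451 ± 5.54 and 817 ± 52.5, Act57B, at 6721 ± 146 and 10070 ± 921, bt and Msp300 did not pass singly. The insulin and TOR signalling list, with a median of 0.15 over 17 genes and 0 passing on either count, was higher (camera adjusted p = 0.041; adjusted p = 0.95 with an estimated correlation). It held Thor, a translation repressor gene, at 569 ± 48.2 and 903 ± 15.9 (adjusted p = 0.074), gig, Nprl2 and foxo, and it passed in 12 of 24 other settings. The muscle and the insulin lists did not pass after quantile normalization (adjusted p = 0.074 and 0.060), where their medians were 0.42 and 0.32. Relative to the median of all genes tested, the muscle list went from 0.53 to 0.35 and the insulin list from 0.22 to 0.25. The ribosomal protein list, which still passed, went from 0.35 to 0.19.

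Proteasome subunit genes were lower as a list, with changes below 0 in 21 of 21 and a median of -0.44 (camera adjusted p = 0.00016; adjusted p = 0.95 with an estimated correlation). Over all genes 0 passed, and 8 fell adjusted over the list alone. Rpn5 had 210 ± 22.3 and 103 ± 27.4, Rpn1 124 ± 13.8 and 69.3 ± 0.051, Prosbeta1 250 ± 8.10 and 149 ± 0.82 and the assembly chaperone gene Pomp 86.4 ± 11.4 and 54.0 ± 4.31. Testis genes were also lower as a list, with changes below 0 in 11 of 11 and a median of -1.29 (camera adjusted p = 0.0049; adjusted p = 0.95 with an estimated correlation). Over all genes 0 passed, and 4 fell adjusted over the list alone. The male germline tubulin gene betaTub85D had 83.7 and 44.7 in the controls and 21.8 and 11.2 in the mutants, Taf12L 15.5, 7.84, 2.82 and 2.66, soti 26.7, 14.5, 8.63 and 4.93, and the protamine gene ProtB 38.5, 13.3, 9.93 and 6.42 in the same order. Control 1 was the highest of the 4 libraries in these 4 genes. The testis genes Mst84Dc and Mst84Dd went the other way and were not tested, listed at 0 in both controls and at 76.6 and 60.9 and at 35.3 and 26.4 in the mutants, where a 0 can be a failed assembly. The testis list lost its call with assembled and correctly placed transcripts only, with the coverage criterion alone and with every 0 kept as a value. The labels do not give the sex of the larvae.

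**Figure D2:**
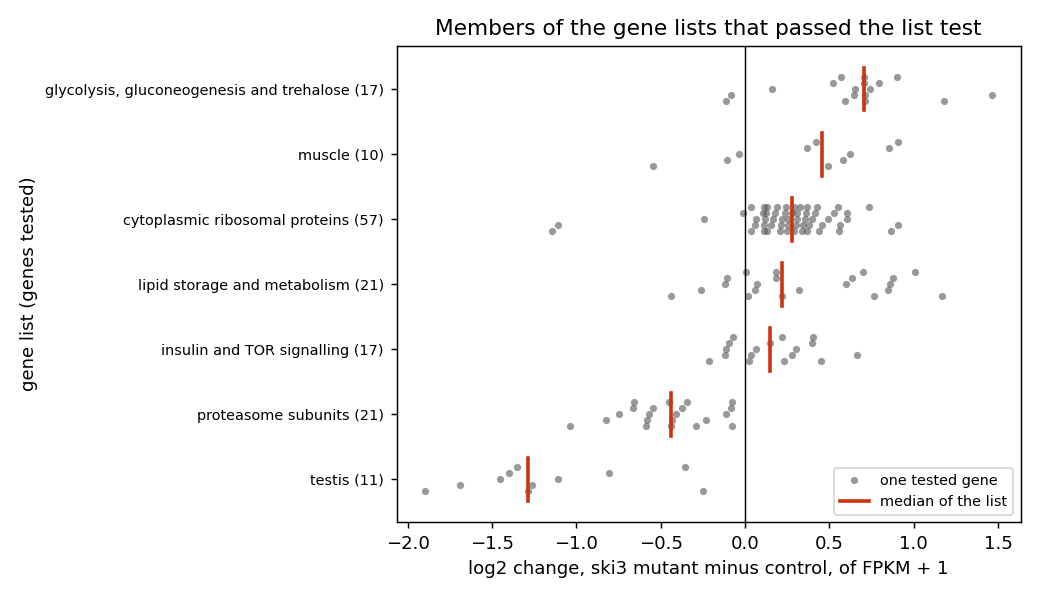
Log2 change of FPKM + 1, mutant minus control, of each tested member of the 7 lists that passed the list test, with 1 grey point per gene, a red line at the median of each list and the number of genes tested in parentheses. Medians lie between -1.29 for the testis list and 0.70 for the glycolysis list, and all 21 proteasome genes and all 11 testis genes lie below 0.

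Cuticle and detoxification genes changed in both directions. Of 27 cuticle protein genes, 2 rose and 6 fell over all genes, 5 rose and 8 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.24). Besides Cpr65Av, Cpr31A fell from 10.9 ± 0.11 to 3.94 ± 0.19, Lcp65Aa from 53.1 ± 5.52 to 21.4 ± 0.98 and Cpr67Fa2 from 46.0 ± 2.75 to 18.8 ± 2.80. Of 56 glutathione S-transferase and other detoxifying genes, 2 rose and 3 fell over all genes, 10 rose and 14 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.60). Cyp4e3 and Cyp4d1, the latter from 71.4 ± 12.3 to 173 ± 9.31, rose, and Cyp4d8, from 20.0 ± 4.18 to 1.96 ± 0.11, and Ugt35C1, from 13.1 ± 1.20 to 5.18 ± 0.64, fell. Of the other settings in which any gene passed, Cyp4e3 passed in 19 of 19, Cyp4d8 in 13 of 18, Cyp4d1 in 11 of 18 and Ugt35C1 in 9 of 19.

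In all, 29 lists were tested, 5 were higher, 2 were lower and 22 did not pass, with adjusted p from 0.10 for ribosome biogenesis (16 genes, median 0.11) to 0.89 for hemocytes. No call held with an estimated correlation. The estimate was -0.053 for glycolysis and 0.012 for lipid metabolism, against the preset 0.01. Correlation between genes therefore does not account for the loss of these calls. With an estimate, camera rests on the few residual degrees of freedom of 4 libraries, so any list is hard to pass. At the preset correlation it rests on the many genes, so those p-values do not reflect how few libraries there were. For ribosomal proteins (0.090 over 57 genes), muscle (0.18), insulin and TOR signalling (0.31), the proteasome (0.37) and testis (0.65), correlation can also matter. Single members that passed in lists that did not were ImpE2 and ImpE3 (lower) of 11 genes of the ecdysone list, Atg9 (higher) of 15 autophagy genes, LysX of 12 antimicrobial genes, hop (lower) of 5 of the JAK-STAT list, CG6287 (lower) of 8 of serine synthesis and one-carbon metabolism, COX6AL (lower) of 46 of oxidative phosphorylation, Lsp1alpha (lower) of 8 fat body storage genes and ng2 (lower) of 8 salivary gland genes. Apart from LysX and ImpE2, these members were named after their values were seen. In the lists of mRNA decay from the 5' end and nonsense-mediated decay (20 genes), heat shock proteins (10), the unfolded protein response (14), mitochondrial ribosomal proteins (26), the juvenile hormone pathway (6), digestive enzymes (24), hemocytes (14), the nervous system (9), DNA replication (16) and apoptosis (11), 0 passed over all genes. The germline and sex-specific lists had 3 tested genes each, of which 0 passed, and were not tested as lists.

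No excess of genes that passed was detected around the Ski3 locus. Within 2 Mb of it, 4 of 142 tested genes passed (2.82%), against 122 of 5097 elsewhere (2.39%), an odds ratio of 1.18 (Fisher's exact test, two-sided, p = 0.59). The share that passed differed between arms, with 1.41% on 2L, which held the most tested genes, 2.43% on 2R and 4.17% on 3L.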

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

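Alternatives called added were chosen after seeing the data, and so were the gene value and the criteria for a measured gene. Counts are genes higher and lower in the mutants, against 50 and 76. They were 33 higher without a filter on the mean, 22 and 46 without the variance trend, 107 higher with quantile normalization, 8 and 19 with the most abundant transcript, and 0 and 0 at an adjusted p of 0.01 with limma, where 1334 genes had an unadjusted p under 0.05. Among the added alternatives they were 15 and 29 with the sum of assigned transcripts, 33 and 50 with assembled and correctly placed transcripts only, 5 and 4 with the coverage criterion alone, 11 and 11 with a value above 0 in all 4 libraries, and 29 and 37 with transcript names as deposited. Of the reported genes, 3 higher and 2 lower were also called with the coverage criterion alone. Keeping every 0 as a value gave 52 and 70, of which 5 and 7 were reported genes, so the like counts hold mostly different genes. Requiring 80% for both criteria gave 51 and 78, of which 34 and 55 were reported genes. Leaving out 1 library gave 0 genes in either direction for each of the 4 libraries, where 1 group then holds 1 library that is assumed to vary like the other group, and no odds ratio around Ski3. On simulated values with 1 control left out, the gene test recovered 2.0% of log2 changes of 1, 56.0% of 2 and 78.4% of 3. The simulation planted equal numbers of changes of 1, 2, 3 and 5, while the 126 reported genes had a median size of 1.41. It therefore does not decide whether the smaller number of libraries is the cause of the count of 0. Apart from the stricter threshold, the cause was not tested.

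The replicate block gave 193 genes higher and 552 lower. The numbers are not shown to pair the libraries, as the differences between replicates 1 and 2 of both groups correlated across genes at r = 0.27 with 2 pairs. The block changed no list call. Lists numbered 5 higher and 2 lower. They were 3 and 4 with quantile normalization, where insulin and TOR signalling (adjusted p = 0.0603) and muscle (0.0735) no longer passed, with medians of 0.32 against 0.15 and of 0.42 against 0.46, and the salivary gland (0.0182) and cuticle (0.0491) lists passed as lower. With an estimated correlation in camera 0 and 0 passed (adjusted p = 0.835 for ribosomal proteins, 0.743 for lipid metabolism, 0.566 for glycolysis and 0.952 for insulin and TOR signalling, the proteasome, muscle and testis). The estimate was -0.053 for glycolysis, 0.012 for lipid metabolism and 0.090 for ribosomal proteins. It was 0.18 for muscle, 0.31 for insulin and TOR signalling, 0.37 for the proteasome and 0.65 for testis. With fry, which asks whether a list moves 1 way on balance, 2 and 0 passed (adjusted p = 0.359 for insulin and TOR signalling, 0.125 for ribosomal proteins, 0.185 for the proteasome, 0.222 for muscle and 0.300 for testis). Insulin and TOR signalling did not pass with a mean of at least 5 (0.0988), with the most abundant transcript (0.0851) or at a threshold of 0.01 (0.0414).

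Among the added alternatives, insulin and TOR signalling and testis did not pass with assembled and correctly placed transcripts only (0.0996 and 0.0615; 4 lists higher and 1 lower), with the coverage criterion alone (0.0551 and 0.0551; 1 lower) or with every 0 kept (0.107 and 0.281; 1 lower). With 80% for both criteria, 3 lists were higher, without insulin and TOR signalling (0.128) and muscle (0.287). With a value above 0 in all 4 libraries, ribosome biogenesis passed as higher (0.0393) and the ecdysone list as lower (0.0368). With transcript names as deposited, which do not measure the named genes on most arms, 2 were higher and 1 lower. Insulin and TOR signalling (0.382), lipid metabolism (0.250), muscle (0.0790) and testis (0.140) did not pass. Whether a list passed or not, these values bear on it only through members on arms where names match positions, such as 2L. Leaving out 1 library gave 3 to 5 lists higher and 2 to 3 lower, with adjusted p from 0.0127 to 0.222 (without control 1) for insulin and TOR signalling and from 0.00117 to 0.0623 (without mutant 2) for muscle, and without control 1 the salivary gland list passed as lower (0.0311). Apart from the deposited names, glycolysis and lipid metabolism passed in 23 of 24 other settings, and ribosomal proteins and the proteasome in 22 each. The median change of all genes moved from -0.07 to 0.07 with quantile normalization. No named gene or list that passed changed its sign. The odds ratio around Ski3 passed the threshold in no setting that gave one. Without read counts, the limits set by depth could not be computed.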

Other observations

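The single genes named in the first 2 paragraphs, roX2, Mst84Dc and Mst84Dd were chosen after their values were seen, and so were the counts of genes listed at 0, the comparison of roX2 with the testis list, the bootstrap interval of the glycolysis list and its comparison with the muscle list. The tanning genes were chosen after ebony and ple were seen and before their own values were, and Pu and Ddc were singled out among them afterwards. Values are in the order control 1, control 2, mutant 1 and mutant 2. Of 8 tested salivary gland genes 6 had changes below 0, with a median of -0.67, and of 8 storage protein genes of the fat body 5 had changes above 0, and neither list passed. The glue gene Sgs8 had 6711, 9310, 3418 and 3051 FPKM (limma adjusted p = 0.060), Eig71Ee 568, 878, 213 and 293 (adjusted p = 0.072), and the new glue gene ng2 fell, with 599, 640, 244 and 179 (adjusted p = 0.043), while ng3 went the other way with 687, 736, 1120 and 1077 (adjusted p = 0.075). The storage protein gene Lsp1alpha fell, with 3334, 3678, 981 and 837 (adjusted p = 0.022), and Lsp1gamma had 3837, 3572, 2889 and 2850 (adjusted p = 0.18). The camera test gave an adjusted p of 0.12 for the salivary gland list and of 0.87 for the storage list, whose median change of 0.22 and mean of -0.079 differ in sign.

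Of 24 tested digestive enzyme genes of the gut, 8 had changes above 0 and 16 below, with a median of -0.23, and the list did not pass (camera adjusted p = 0.88). The amylase gene Amy-p had 17.2, 11.4, 82.2 and 208 FPKM (limma adjusted p = 0.057), and its near-identical copy Amy-d, with which reads can be shared, 28.8, 16.5, 44.4 and 89.4. The protease gene Jon25Bi had 986, 689, 276 and 329 (adjusted p = 0.056) and Jon25Biii 3091, 1885, 1062 and 1219 (adjusted p = 0.11). The antifungal peptide-like gene Drsl2 had 53.3, 3.73, 839 and 1113 (adjusted p = 0.079), and its 2 controls differ widely. Besides these, 39 genes measured at 10 FPKM or more in both controls were listed at 0 in both mutants, among them epsilonTry with 4596 and 3435 and LysD with 1782 and 1301, and 24 were listed at 0 in both controls and at 10 FPKM or more in both mutants, among them Muc55B with 155 and 121, the testis gene Mst84Dc with 76.6 and 60.9, Set with 50.8 and 49.0, and Ubc7 with 48.7 and 49.0. Between 2 and 13 genes were listed at 0 in the 4 pairs of 1 control and 1 mutant. Housekeeping genes such as Rheb, with 59.7 and 60.2 in the controls, are among the 39, so these zeros were not read as absent expression.

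The lower values of ebony, ple and ImpE2 in mutants raise the hypothesis that the control larvae were nearer to pupariation when collected, with changes over the other settings from -4.24 to -3.01 for ple, whose call held in 6 of the 18 in which any gene passed, from -7.36 to -5.17 for ebony (e) and from -3.06 to -2.51 for ImpE2. Of 7 measured genes of cuticle tanning other than ebony and ple, 6 had changes below 0, with a median of -0.63, and 1 passed, the GTP cyclohydrolase gene Pu, with 55.3, 57.2, 15.5 and 11.8 FPKM (limma adjusted p = 0.024). This is consistent with a difference in stage. In Ddc, a tanning gene with a change below 0, the groups overlapped, with 43.2, 91.1, 16.0 and 56.4 FPKM. Of the fixed lists, the ecdysone list had 8 of 11 changes below 0 and a median of -0.21, and did not pass (camera adjusted p = 0.24). The cuticle (0.24) and salivary gland (0.12) lists did not pass either. Whether a difference in stage comes from slower development of the mutants or from the time of collection was not tested. A direct effect of the mutation on ebony, ple, ImpE2 and the tanning genes stays open.

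The lower values of the 11 tested testis genes may reflect fewer males among the mutant larvae. Against this, the untested testis genes Mst84Dc and Mst84Dd were listed at 0 in both controls and at 76.6 and 60.9 and at 35.3 and 26.4 in the mutants, but a 0 can be a failed assembly, so they do not decide. The male-specific RNA roX2 had 13.4, 7.70, 5.45 and 7.94 FPKM (limma adjusted p = 0.34), a change of -0.56 against a mean of -1.17 for the testis list. The difference of 0.61 had a 95% interval from -1.70 to 2.92 over the 4 libraries, so a smaller share of males and a smaller output of the testis cannot be told apart. The wide interval with 2 libraries per group keeps this open. Whether a difference in stage or in background contributes to the lower testis values was not tested.

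The glycolysis list was higher with camera at a preset correlation of 0.01, but not with an estimated one of -0.053 (adjusted p = 0.57). The changes of its genes do not come from the scaling between libraries alone, since their median was 0.70 and, after quantile normalization, 0.78, with a 95% bootstrap interval over genes from 0.62 to 0.82. Relative to the median of all genes tested it went from 0.78 to 0.71. A larger share of muscle in the mutant larvae may contribute. The median of the glycolysis list exceeded that of the muscle list by 0.25, with a 95% bootstrap interval over genes from -0.028 to 0.74, so this stays open, as does a change in metabolism itself. Both intervals resample genes of the same libraries and leave out the spread between libraries. Whether a difference in stage or in background contributes to the higher glycolysis values was not tested.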
